A study of Homo sapiens with 17 samples.

How the data were processed

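Total RNA from MOLM13 cells had been made into stranded libraries after depletion of ribosomal RNA, and sequenced in pairs of 150-base reads on a HiSeq instrument. The processing notes name Trim Galore, STAR 2.7.10a, HTSeq 1.99.2, bedtools and the genome hg38; the strand setting of the counts and the annotation release are not given in the sources used here. The deposited values were whole-number counts per gene, 58278 gene identifiers in each of the 17 libraries, with further lines for reads outside genes and reads in more than 1 gene. Counts of the 9 libraries of the HOXA9 and SAFB experiment and of the 8 libraries of the MEIS1 experiment had the same layout. Names and GRCh38 coordinates came from GENCODE 29, which holds 57940 of the identifiers; 57392 were found in a table of current symbols, 338 had no symbol, and 45 were copies on the Y chromosome's pseudoautosomal region. The labels do not state whether libraries of a group came from separate cultures or clones, so the p-values measure the spread between libraries as deposited. How the guides acted on each gene is not given in the sources used here, and a frameshift need not lower the RNA.

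Each comparison was fitted with edgeR 4.0.16 under R 4.3.3. Genes were filtered with filterByExpr (at least 10 counts in enough libraries and 15 in total), scaled by TMM and tested with the robust quasi-likelihood F test. The 9 libraries of the HOXA9 and SAFB experiment formed 1 fit, the 8 of the MEIS1 experiment another, and all 17 a fit for the tests of whether 2 knockout effects differ. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05; only called genes are said to rise or fall. The SE of a log2 fold change is its size divided by the root of the F statistic. Common biological coefficients of variation were 4.63% and 6.75% in the first 2 fits. Shared genes are those called in 2 comparisons in the same direction, set beside the number that independent calls would share. That number gives every tested gene the same chance of a call, whatever its level. Exon overlap with other genes was computed from GENCODE 29.

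Gene lists, comparisons, the rule for named genes and the alternatives were fixed before the data were examined. The 23 lists covered monocyte and granulocyte differentiation, immature granules, the HOXA/MEIS1 and MLL-fusion programme, 4 genes recalled from the study, the Notch pathway, p53 targets, G2/M, replication and E2F targets, MYC targets, ribosomal proteins, interferon response, TNF and NF-kB, MHC class II, immediate-early genes, apoptosis regulators, unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded mRNAs, replication-dependent histones, chromatin repressors that associate with SAFB or HOXA9, and markers of erythroid and megakaryocyte and of lymphoid cells. The 22 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, each adjusted over the lists. A list passed when the adjusted p at the preset correlation was under 0.05; the value with an estimated correlation is given beside it. Some lists share members: 9 apoptosis regulators and 7 p53 targets are also in another list, and each of the 4 recalled genes is too. The HOXA/MEIS1 list holds HOXA9 and MEIS1 themselves, whose falls in their own knockouts are no evidence on the rest of the programme.

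Named genes followed a rule. In each knockout comparison these were HOXA9, SAFB, MEIS1, SAFB2, SLTM, PBX3, HOXA7 and HOXA10; the 10 largest rises and the 10 largest falls among called genes with a symbol that is neither clone-based nor a pseudogene, a mean of at least 2 CPM in the higher group and separated groups; up to 4 members of each list by the smallest p, some left out where the list's count is given; and the 4 recalled genes NOTCH1, CEBPD, S100A8 and CDKN1A. For HOXA9_KO against SAFB_KO and for the differences between effects the 5 largest each way were named, without the condition on separated groups for the latter, and for shared genes the 10 with the largest smaller change each way.

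Alternatives changed a single choice at a time: RLE factors, no filter, a mean of at least 2 CPM, DESeq2 1.42.0, limma-voom, a term for the replicate number, other libraries in the fit, an adjusted p under 0.01 for shared genes, an estimated correlation for lists and leaving out each library in turn. Scaling to the counts of nuclear protein-coding genes and a mean of at least 20 CPM were chosen after seeing the data. The method was tested on simulated counts with 200 genes changed. Every group was given the mean levels of its experiment's non-targeting libraries, also for HOXA9_KO against SAFB_KO, and the spread of the fit. Of genes changed by 0.5 and 1 on the log2 scale, edgeR recovered 63.5% and 75.3% for HOXA9_KO, 68.8% and 75.8% for SAFB_KO and 72.0% and 88.7% for MEIS1_KO. It recovered 55.8% and 70.7% for HOXA9_KO against SAFB_KO, and 48.5% and 62.0%, and 46.5% and 62.9%, for the 2 differences between effects. Of the unchanged genes it called 17 of 18062, 21 of 18106, 15 of 15167, 22 of 17997, 11 of 18115 and 15 of 18199. A list shifted on purpose passed camera in all 6 comparisons, with at most 1 of 21 other lists. Simulated genes were drawn independently of each other. The simulation therefore does not show how often lists of correlated genes pass without an effect at the preset correlation. Far fewer genes were changed in it than were called in the data, so its recovery shares can be too low. Figures were drawn with matplotlib 3.10.9.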

Results

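RNA sequencing was carried out on MOLM13 cells, an established human acute myeloid leukaemia line that carries the MLL-AF9 fusion oncoprotein. The 17 libraries formed 2 experiments. In the HOXA9 and SAFB experiment, 3 libraries came from cells with a non-targeting guide (NT), 3 from cells with a HOXA9 knockout (HOXA9_KO) and 3 from cells with a SAFB knockout (SAFB_KO). In the MEIS1 experiment, 4 libraries with a non-targeting guide (NT_MEIS1ex) stood beside 4 with a MEIS1 knockout (MEIS1_KO). HOXA9 and MEIS1 are homeobox transcription factors of the MLL-fusion leukaemia programme, and SAFB is a nuclear matrix protein that binds DNA and RNA.

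Reads assigned to genes numbered 67.8, 42.7 and 39.9 M in the NT libraries, 36.2, 38.9 and 42.5 M in the HOXA9_KO libraries and 30.7, 44.4 and 35.0 M in the SAFB_KO libraries. The NT_MEIS1ex libraries held 28.2, 27.1, 26.8 and 33.2 M and the MEIS1_KO libraries 29.9, 27.8, 26.8 and 23.3 M. Mitochondrial rRNA genes took 25.1% ± 3.02 (SD, n = 3) of the assigned reads in NT, 33.9% ± 1.81 in HOXA9_KO and 25.7% ± 1.15 in SAFB_KO, against at most 0.0101% in any library of the MEIS1 experiment. Reads outside annotated genes made up 17.04% ± 0.957 (SD, n = 3) in NT, 9.02% ± 0.325 in HOXA9_KO and 11.6% ± 1.05 in SAFB_KO. In NT_MEIS1ex and MEIS1_KO they made up 7.30% ± 0.993 and 8.25% ± 0.685 (SD, n = 4). Levels below are CPM (counts scaled to library size) after TMM scaling, given as the mean and its SD over libraries, and changes are log2 fold changes ± SE.

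The targeted genes were examined in every library before the comparisons, with CPM scaled within each experiment. Control levels differed between the experiments. SAFB lay at 132, 98.4, 105.0 and 103.9 CPM in NT_MEIS1ex, and MEIS1 at 48.4, 48.6 and 50.4 CPM in NT. HOXA9 (ENSG00000078399.17, GRCh38 chromosome 7, 27162435 to 27175180, minus strand) lay at 40.5, 42.0 and 40.1 CPM in NT and at 21.9, 21.2 and 21.1 CPM in HOXA9_KO, a fall of 0.93 ± 0.05 on the log2 scale (adjusted p 1.4e-20). In SAFB_KO it lay at 38.2, 36.9 and 38.3 CPM. SAFB (ENSG00000160633.12, chromosome 19, 5623035 to 5668478, plus strand) lay at 40.4, 33.6 and 40.9 CPM in NT and at 22.2, 20.4 and 19.4 CPM in SAFB_KO, a fall of 0.89 ± 0.07 (adjusted p 5.9e-14). In HOXA9_KO, SAFB lay at 33.4, 35.6 and 37.5 CPM. MEIS1 (ENSG00000143995.19, chromosome 2, 66433452 to 66573869, plus strand) lay at 31.8, 32.8, 31.7 and 33.4 CPM in NT_MEIS1ex and at 10.6, 10.3, 12.8 and 10.98 CPM in MEIS1_KO, a fall of 1.54 ± 0.07 (adjusted p 1.0e-09). In each of the 3 knockouts the targeted gene was lower in every knockout library than in every control library. A gene-level count cannot show how much of the remaining RNA codes for the full protein, and 15.9% of the exon sequence of HOXA9 also belongs to another gene of the same strand.

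**Figure D1:**
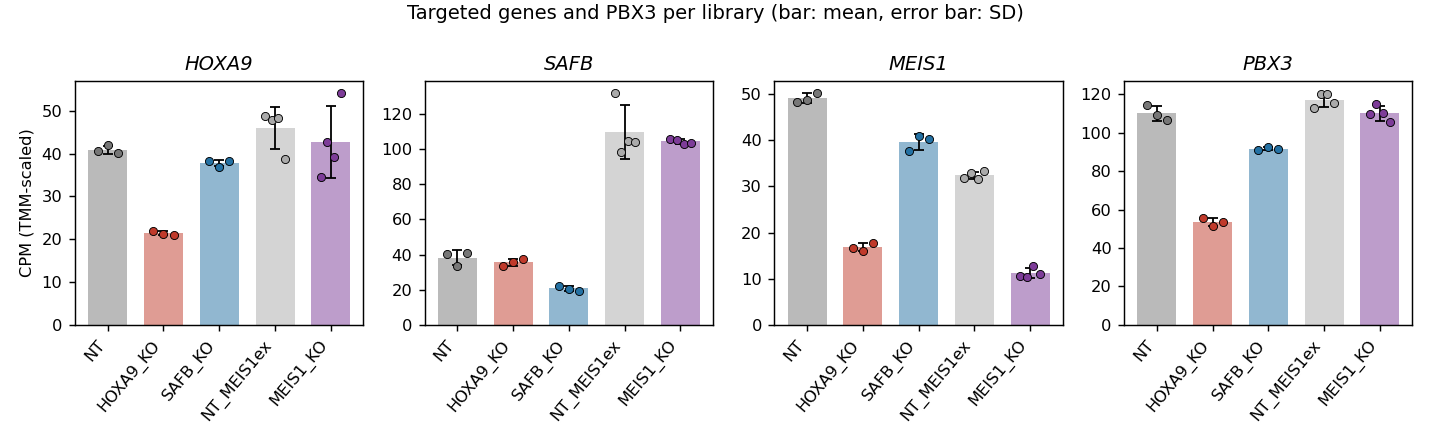
Levels of HOXA9, SAFB, MEIS1 and PBX3 in CPM (y axis) in each of the 5 groups (x axis); points are libraries, bars are means and error bars are SD. HOXA9, SAFB and MEIS1 are lowest in their own knockouts, and MEIS1 also falls from 49.1 to 16.8 CPM and PBX3 from 110 to 53.6 CPM when HOXA9 is targeted. CPM was scaled within each experiment.

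Relative to NT, HOXA9_KO had higher myeloid expression and lower expression of the leukaemia and cell cycle programmes. Genes of monocytes and granulocytes rose, and so did immature granule genes and p53 target genes. HOXA/MEIS1 programme genes, cell cycle genes and histone genes fell. Interferon-response genes were lower than in NT libraries in which they stood high, at the preset correlation but not with an estimated one (adjusted p = 0.0684 with an estimated correlation). The comparison asks which genes depend on HOXA9 in these cells.

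Among 40 tested genes of monocyte and granulocyte differentiation, 39 rose, with a median log2 change of 1.67 (camera adjusted p 3.4e-77; adjusted p = 9.7e-04 with an estimated correlation). Counts of list members are over all genes tested, and where no further count follows in brackets the count adjusted over the list alone was the same. CYBB, the catalytic subunit of the phagocyte oxidase, rose by 2.71 ± 0.04 from 59.9 to 392 CPM, and the endosomal receptor TLR8 rose by 3.23 ± 0.05 from 15.9 to 149 CPM. S100A9, a calcium-binding protein of neutrophils and monocytes, rose by 4.10 ± 0.07 from 5.23 to 90.5 CPM. Of 18 immature granule genes 13 rose and 3 fell (median 0.77, adjusted p 1.1e-15; adjusted p = 0.0164 with an estimated correlation). SRGN, the proteoglycan of storage granules, rose by 1.97 ± 0.03 from 1635 to 6391 CPM, and myeloperoxidase (MPO) rose by 2.48 ± 0.06 from 16.8 to 93.6 CPM.

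In the list of HOXA/MEIS1 and MLL-fusion programme genes, 27 of 34 fell and 4 rose (median −0.75, adjusted p 7.9e-12, and adjusted p = 0.00434 with an estimated correlation). HOXA9, the targeted gene, is a member and among the falls. MEIS1 itself fell by 1.54 ± 0.06 from 49.1 ± 1.06 to 16.8 ± 0.816 CPM (SD, n = 3; adjusted p 9.4e-29), and PBX3 (chromosome 9, 125747345 to 125967377), which encodes a dimer partner of HOXA9, fell by 1.04 ± 0.04. The survival gene BCL2 fell by 1.71 ± 0.04 from 167 to 50.9 CPM, MEF2C by 1.39 ± 0.03 from 378 to 144 CPM and the receptor kinase FLT3 by 1.07 ± 0.03 from 675 to 321 CPM. The neighbouring homeobox genes HOXA7 and HOXA10 fell by 1.32 ± 0.24 and 0.89 ± 0.09; 9.93% of the exon sequence of HOXA10 also belongs to another gene of its strand. SAFB changed by −0.11 ± 0.06 (adjusted p 0.151, range over the alternatives 1.5e-05 to 0.493), and passed at a mean of at least 2 CPM (−0.16, adjusted p 0.0286), at a mean of at least 20 CPM (−0.21, 0.00981), without NT replicate 2 (−0.19, 0.00951) and scaled to nuclear protein-coding counts (−0.36, 1.5e-05). The 20 CPM filter rescales the libraries, and the median of genes at that level went from 0.10 to −0.01 with it. The relatives of SAFB changed by 0.11 ± 0.06 (SAFB2, adjusted p 0.101) and by 0.08 ± 0.04 (SLTM, adjusted p 0.0572). The last 2 genes depended on the alternative, with adjusted p ranging over 0.0233 to 0.971 for SAFB2 and 7.7e-05 to 0.550 for SLTM. Both were higher with RLE factors (0.14, adjusted p 0.0293, and 0.12, adjusted p 0.00725), with DESeq2 (0.0446 and 0.0101) and in a fit of only the compared groups (0.0299 and 0.0109), and SLTM also with limma-voom (0.0480) and without NT replicate 2 (0.0279), HOXA9_KO replicate 1 (0.0344), SAFB_KO replicate 1 (0.0478) or SAFB_KO replicate 3 (0.0280). Both were lower, at −0.14 and −0.17, when libraries were scaled to their nuclear protein-coding counts, a scaling chosen after seeing the data.

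All 4 genes recalled from the study as repressed by HOXA9 and SAFB rose. Because they were recalled from it, their count is not independent evidence. The cell cycle inhibitor CDKN1A rose by 2.02 ± 0.03 from 223 to 902 CPM, S100A8 by 3.79 ± 0.08 from 3.28 to 45.3 CPM, NOTCH1 by 1.11 ± 0.04 from 62.0 to 133 CPM and the transcription factor gene CEBPD by 1.71 ± 0.07 from 10.8 to 35.5 CPM. Of 25 Notch pathway genes 15 rose and 4 fell (17 and 4 adjusted over the list alone). Their median was 0.38 (adjusted p 0.0107; adjusted p = 0.202 with an estimated correlation). NOTCH2 rose by 1.63 ± 0.03 from 106 to 330 CPM, while the ligand genes JAG1 and DLL1 fell by 0.81 ± 0.04 and 1.96 ± 0.09. Of 31 p53 target genes 29 rose and 1 fell (median 0.71, adjusted p 5.1e-16; adjusted p = 0.0109 with an estimated correlation). MDM2, which encodes the ligase that degrades p53, rose by 1.22 ± 0.03 from 356 to 832 CPM and TP53INP1 by 1.69 ± 0.05. Apoptosis regulators went both ways, with 18 of 34 higher and 9 lower (18 and 10 adjusted over the list alone), and their list did not pass (adjusted p 0.272).

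Genes of the cell cycle fell nearly throughout. Of 35 G2/M genes 34 fell (median −0.94, adjusted p 6.9e-30; adjusted p = 0.0109 with an estimated correlation), among them TOP2A by 1.16 ± 0.03 from 348 to 156 CPM and the spindle motor gene KIF11 by 1.13 ± 0.04. Of 40 DNA replication and E2F target genes 39 fell (median −0.76, adjusted p 6.4e-20; adjusted p = 0.00434 with an estimated correlation), with MCM7 down by 0.75 ± 0.03 and RRM2 by 1.02 ± 0.04. Replication-dependent histone genes followed, with 32 of 35 lower (33 adjusted over the list alone; median −0.84, adjusted p 6.3e-26; adjusted p = 0.0109 with an estimated correlation). H2AC14 fell by 1.19 ± 0.04 and H1-5 by 0.85 ± 0.03. MYC targets and ribosome biogenesis genes split into 9 higher and 12 lower of 40 and did not pass (adjusted p 0.430, range over the alternatives 0.0108 to 0.641), except as lower when scaled to nuclear protein-coding counts (median −0.29, adjusted p 0.0108). Cytosolic ribosomal protein genes rose in 49 of 50 cases by a median of 0.40 (adjusted p 2.2e-14; adjusted p = 0.162 with an estimated correlation). RPLP2 rose by 0.78 ± 0.03 and RPS19 by 0.76 ± 0.03, in libraries whose rRNA genes took 33.9% of the reads against 25.1% in NT. Reads of ribosomal protein and histone genes can also fit their pseudogenes or paralogs. Of the 13 mitochondrially encoded mRNAs 6 rose, and the list did not pass (adjusted p 0.177, range 0.0181 to 0.669) except without NT replicate 1 (0.0181).

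The interferon-response list fell in 47 of 49 genes, with a median of −2.46 (adjusted p 5.4e-34; adjusted p = 0.0684 with an estimated correlation), and 2 genes rose. IFI44L fell by 4.70 ± 0.24 from 130 to 5.08 CPM, IFI27 by 4.18 ± 0.13 from 24.9 to 1.35 CPM, IRF7 by 2.07 ± 0.06 from 55.6 to 13.3 CPM and DDX60 by 2.46 ± 0.06 from 97.3 to 17.6 CPM. The mean log2 level of this list was 5.77 ± 0.206 (SD, n = 3) in NT, 3.61 ± 0.0487 in HOXA9_KO and 4.07 ± 0.0786 in SAFB_KO, and 3.99 ± 0.158 (SD, n = 4) in NT_MEIS1ex, the controls of the MEIS1 experiment. TNF and NF-kB genes rose in 19 of 33 cases and fell in 8 (20 and 8 adjusted over the list alone; median 0.45, adjusted p 0.00199; adjusted p = 0.0573 with an estimated correlation), a call also lost at a mean of at least 20 CPM (0.170, range 2.0e-04 to 0.170). TNFAIP2 rose by 1.23 ± 0.05 and IL1B by 1.97 ± 0.11 from 3.07 to 12.1 CPM, while CCL5 fell by 0.99 ± 0.05. MHC class II genes split into 9 higher and 3 lower of 16 (adjusted p 0.0628, range 0.0265 to 0.382). The list passed as higher without NT replicate 1 (0.0480) or 3 (0.0265), HOXA9_KO replicate 2 (0.0402), or SAFB_KO replicate 1 (0.0445), 2 (0.0439) or 3 (0.0486). HLA-DMA rose by 1.29 ± 0.07 and the lysosomal protease gene CTSS by 1.04 ± 0.03, while the transactivator gene CIITA fell by 1.27 ± 0.07. Immediate-early genes, of which 12 rose and 9 fell of 28 (13 and 9 adjusted over the list alone), did not pass (median 0.05, mean −0.03, adjusted p 0.177).

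Metabolic and stress lists moved less evenly. The unfolded protein and integrated stress list held 15 higher and 14 lower genes of 30. Its median was 0.10, −0.16 when scaled to nuclear protein-coding counts, while its mean was −0.37 and its test pointed down (adjusted p 1.4e-05; adjusted p = 0.0409 with an estimated correlation). The asparagine synthetase gene ASNS fell by 2.65 ± 0.07 from 68.4 to 10.9 CPM, PHGDH of serine synthesis by 2.33 ± 0.05 from 125 to 24.8 CPM and XBP1 by 1.59 ± 0.04 from 236 to 78.1 CPM. Cholesterol synthesis genes fell in 18 of 23 cases and 1 rose (median −0.32, adjusted p 4.1e-06; adjusted p = 0.0321 with an estimated correlation), with FDPS down by 1.08 ± 0.03. Glycolysis and hypoxia genes, 15 higher and 11 lower of 31 (16 and 11 adjusted over the list alone), did not pass (adjusted p 0.151), although PKM rose by 1.58 ± 0.03 from 653 to 1955 CPM. Among 28 genes of chromatin repressors that associate with SAFB or HOXA9, 7 rose and 13 fell, EZH2 by 0.92 ± 0.05, and the list did not pass (adjusted p 0.177, range 0.00484 to 0.384), except as lower when scaled to nuclear protein-coding counts (0.00484). Lists of other cell types did not pass either: 1 of 8 erythroid and megakaryocyte genes rose and 1 fell (adjusted p 0.646), and 3 of 12 lymphoid genes rose and 6 fell (adjusted p 0.151).

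By the rule for named genes, the largest rises in HOXA9_KO were those of the U6 RNA gene RNU6-1 (6.51 ± 0.15), the anion transporter gene SLC26A11 (5.33 ± 0.24), the sterol hydroxylase gene CYP27A1 (5.10 ± 0.19, from 0.313 to 10.4 CPM), CHI3L1 (4.68 ± 0.03), APOE (4.66 ± 0.29) and the lipopolysaccharide co-receptor gene CD14 (4.60 ± 0.35, from 0.114 to 2.79 CPM). They were followed by CRISPLD2 (4.56), the small nucleolar RNA gene SNORA53 (4.47), the IgA receptor gene FCAR (4.45 ± 0.13) and MGAM2 (4.31 ± 0.06). CHI3L1, which encodes a secreted glycoprotein of macrophages, reached 1913 CPM from 74.5 CPM (adjusted p 8.7e-59). The largest falls were those of IFITM1 (−5.51 ± 0.36), OTOF (−4.79), IFI44L (−4.70), CXCL11 (−4.64), USP18 (−4.37), MAP1A (−4.33 ± 0.15), EVPL (−4.30), IFI44 (−4.24), IFI27 (−4.18) and JUP (−4.15). Of the exon sequence of IFITM1, 32.5% also belongs to another gene of its strand.

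In edgeR's quasi-likelihood test of 18876 genes, 5207 were higher and 5640 lower in HOXA9_KO at an adjusted p under 0.05, and 957 and 1957 of them changed at least 2-fold. In 62.6% of the tested genes every library of one group lay above every library of the other, which chance gives in 10% of genes for 3 against 3. Scaling to nuclear protein-coding counts shifted the median of all genes by −0.25 and gave 2861 higher and 9293 lower genes, so that 23.5% and not 48.0% of the calls were higher. Under that scaling myeloid genes stood at a median of 1.41, p53 targets at 0.45, ribosomal protein genes at 0.15 and G2/M genes at −1.19. Genes with a mean under 1 CPM had a median of −0.46 and those of at least 20 CPM a median of 0.10, while reads outside annotated genes fell from 17.04% to 9.02%.

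Many of the myeloid and p53 genes that rose in HOXA9_KO also rose in SAFB_KO, mostly by less. Interferon-response genes fell, and the unfolded protein and integrated stress list was lower with members both ways. G2/M, E2F, histone and HOXA/MEIS1 programme genes were lower by small amounts at the preset correlation, and not past the threshold with an estimated one (adjusted p = 0.134, 0.169, 0.0570 and 0.0958 with an estimated correlation). The comparison asks which genes depend on SAFB, whose complex with HOXA9 the study's title describes as repressive.

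Of 40 monocyte and granulocyte genes 34 rose (median 0.62, adjusted p 5.7e-65; adjusted p = 8.3e-04 with an estimated correlation). Where no further count follows in brackets, the count adjusted over the list alone was again the same. The matrix proteoglycan gene VCAN rose by 1.52 ± 0.03 from 146 to 419 CPM, FGL2 by 1.87 ± 0.04 from 47.8 to 176 CPM and CYBB by 1.20 ± 0.03 from 59.9 to 137 CPM. Immature granule genes rose in 12 of 18 cases and fell in 2 (13 and 2 adjusted over the list alone; median 0.19, adjusted p 4.8e-10; adjusted p = 0.0570 with an estimated correlation), SRGN by 0.9996 ± 0.03 and PLAC8 by 0.91 ± 0.03. All 4 recalled genes rose, again as no independent evidence: CDKN1A by 1.06 ± 0.03 to 465 CPM, S100A8 by 2.08 ± 0.09 to 13.9 CPM, NOTCH1 by 0.49 ± 0.04 to 87.0 CPM and CEBPD by 0.65 ± 0.07 to 17.01 CPM. Of 31 p53 target genes 27 rose and 2 fell (28 and 2 adjusted over the list alone; median 0.50, adjusted p 6.2e-22; adjusted p = 0.00631 with an estimated correlation), with MDM2 up by 0.84 ± 0.03 from 356 to 636 CPM. Notch pathway genes split into 14 higher and 6 lower of 25 without passing (adjusted p 0.0903, range 0.0479 to 0.384; 0.0479 without NT replicate 2), NOTCH2 rising by 0.52 ± 0.03 and DLL1 falling by 0.80 ± 0.08. Apoptosis regulators, 13 higher and 8 lower of 34 (14 and 8 adjusted over the list alone), did not pass (adjusted p 0.585).

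In the HOXA/MEIS1 and MLL-fusion list 15 of 34 genes fell and 6 rose (18 and 7 adjusted over the list alone; median −0.17, adjusted p 0.00594; adjusted p = 0.0958 with an estimated correlation). BCL2 fell by 0.65 ± 0.04 and FLT3 by 0.30 ± 0.03, while CDK6 rose by 0.29 ± 0.03. MEIS1 fell by 0.31 ± 0.05 (adjusted p 3.2e-06), PBX3 by 0.27 ± 0.04 and HOXA10 by 0.24 ± 0.08 (adjusted p 0.0227). The HOXA10 call was lost without NT replicate 3 (adjusted p 0.209), without SAFB_KO replicate 2 (0.111) and without SAFB_KO replicate 3 (0.0501), and also with DESeq2 (0.0568), in a range of 3.3e-04 to 0.209 over the alternatives. HOXA9 changed by −0.11 ± 0.05 (adjusted p 0.0762, range 7.0e-05 to 0.244) and passed as lower at a mean of at least 2 CPM (−0.17, adjusted p 0.00541), with limma-voom (−0.12, 0.0458), at a mean of at least 20 CPM (−0.20, 0.00101) and scaled to nuclear protein-coding counts (−0.25, 7.0e-05). The 20 CPM filter rescales the libraries, and the median of genes at that level went from 0.09 to −6.2e-04 with it. HOXA7 changed by 0.10 (adjusted p 0.756, −0.04 when scaled to nuclear protein-coding counts). Over the alternatives it ranged from −0.04 to 0.28 and was never called (adjusted p 0.388 to 0.937). SAFB2, the paralog of SAFB, rose by 0.35 ± 0.06 from 31.5 to 40.2 CPM (adjusted p 8.9e-07). SLTM rose by 0.16 ± 0.04 (adjusted p 3.6e-04) but by 0.02 when scaled to nuclear protein-coding counts (adjusted p 0.641, range 1.1e-04 to 0.641) and by 0.07 at a mean of at least 20 CPM (adjusted p 0.0738).

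Interferon-response genes fell in 47 of 49 cases (median −1.92, adjusted p 8.5e-86; adjusted p = 0.0229 with an estimated correlation), from the same high level in NT. IFI44L fell by 3.53 ± 0.21 from 130 to 11.3 CPM and IRF7 by 1.64 ± 0.06 from 55.6 to 17.9 CPM. In the unfolded protein and integrated stress list 18 of 30 genes fell and 9 rose (median −0.32, adjusted p 1.9e-20; adjusted p = 0.00631 with an estimated correlation). ASNS fell by 2.10 ± 0.06 from 68.4 to 15.9 CPM, PHGDH by 1.60 ± 0.04 from 125 to 41.2 CPM and the transcription factor gene ATF5 by 1.41 ± 0.05 from 85.3 to 32.1 CPM. MHC class II genes fell in 9 of 16 cases and rose in 3 (median −0.40, adjusted p 0.00322; adjusted p = 0.220 with an estimated correlation), a call also lost at a mean of at least 20 CPM (0.355, range 4.7e-04 to 0.355). HLA-DRA fell by 0.83 ± 0.08 and CIITA by 1.19 ± 0.07.

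Of 35 G2/M genes 31 fell (32 adjusted over the list alone; median −0.18, adjusted p 5.0e-08; adjusted p = 0.134 with an estimated correlation), CENPF by 0.42 ± 0.04 and TOP2A by 0.26 ± 0.03. Replication and E2F genes fell in 20 of 40 cases and 1 rose (21 and 1 adjusted over the list alone; median −0.14, adjusted p 0.00322; adjusted p = 0.169 with an estimated correlation). Histone genes fell in 32 of 35 cases (median −0.24, adjusted p 2.4e-12; adjusted p = 0.0570 with an estimated correlation), H2AC8 by 0.59 ± 0.04. Ribosomal protein genes rose in 48 of 50 cases (median 0.34, adjusted p 7.0e-33; adjusted p = 0.0608 with an estimated correlation), RPS24 by 0.49 ± 0.03. MYC targets and ribosome biogenesis genes rose in 22 of 40 cases (23 adjusted over the list alone; median 0.12, adjusted p 0.00455; adjusted p = 0.164 with an estimated correlation). Their list did not pass at a mean of at least 2 CPM (median 0.07, adjusted p 0.197), at a mean of at least 20 CPM (0.524) or scaled to nuclear protein-coding counts (median −0.01, adjusted p 0.309), in a range of 0.00215 to 0.524.

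The remaining lists did not pass in SAFB_KO in the main test. TNF and NF-kB genes split into 12 higher and 8 lower of 33 (16 and 10 adjusted over the list alone; adjusted p 0.686) and immediate-early genes into 7 and 6 of 28 (median 0.03, mean −0.06, adjusted p 0.585), with FOS up by 0.67 ± 0.04 and ATF3 down by 1.45 ± 0.11. Glycolysis and hypoxia genes split into 9 higher and 13 lower of 31 (13 and 13 adjusted over the list alone), with a median of 0.01 but a mean of −0.16 and a test that pointed down (adjusted p 0.0604, range 3.8e-04 to 0.420), and VEGFA and DDIT4 fell by 1.01 ± 0.05 and 1.30 ± 0.08. The glycolysis list passed at a mean of at least 2 CPM (0.0137), at a mean of at least 20 CPM (0.0489), scaled to nuclear protein-coding counts (3.8e-04), without NT replicate 1 (0.0396) and without SAFB_KO replicate 3 (0.0260). Cholesterol synthesis genes held 2 higher and 7 lower of 23 (adjusted p 0.0903, range 6.2e-04 to 0.384). Their list passed as lower at a mean of at least 2 CPM (0.0145), at a mean of at least 20 CPM (0.00340), scaled to nuclear protein-coding counts (6.2e-04) and without NT replicate 1 (0.0396). Chromatin repressor genes held 5 higher and 6 lower of 28 (adjusted p 0.686). None of the 13 mitochondrially encoded mRNAs was called by edgeR, where 1 was lower at an unadjusted p under 0.05; DESeq2 called 1 lower and limma-voom 7 lower and 1 higher, and their list passed as lower without NT replicate 2 (adjusted p 0.0198, range 0.0198 to 0.765). Of 8 erythroid and megakaryocyte genes 1 fell (adjusted p 0.224), and of 12 lymphoid genes 2 rose and 4 fell (2 and 5 adjusted over the list alone; adjusted p 0.403).

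The largest rises in SAFB_KO were those of MGAM2 (3.13 ± 0.06, from 5.10 to 44.8 CPM), FCAR (2.75 ± 0.14), S100A9 (2.34 ± 0.07), GPR82 (2.10), ADGRE3 (2.10), S100A8 (2.08), CLEC1A (1.96), SCG2 (1.95), the scavenger receptor gene MARCO (1.90 ± 0.12, from 2.03 to 7.62 CPM) and TLR8 (1.88 ± 0.05). The largest falls were those of IFITM1 (−3.62 ± 0.27), IFI44L (−3.53), the glycine transporter gene SLC6A9 (−3.38), STC2 (−3.15 ± 0.15), IFI27 (−3.12), ADM2 (−3.02 ± 0.17), IFIT1 (−2.94 ± 0.23), CHAC1 (−2.94 ± 0.16), INHBE (−2.88) and USP18 (−2.84). In all, 3812 of 18876 genes were higher and 2886 lower in SAFB_KO, 193 and 681 of them at least 2-fold. Groups were separated in 46.3% of the tested genes, against 10% by chance. Scaling to nuclear protein-coding counts shifted the median of all genes by −0.14 and gave 1712 higher and 5535 lower genes, or 23.6% higher against 56.9%; myeloid genes then stood at a median of 0.48 and p53 targets at 0.37.

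**Figure D2:**
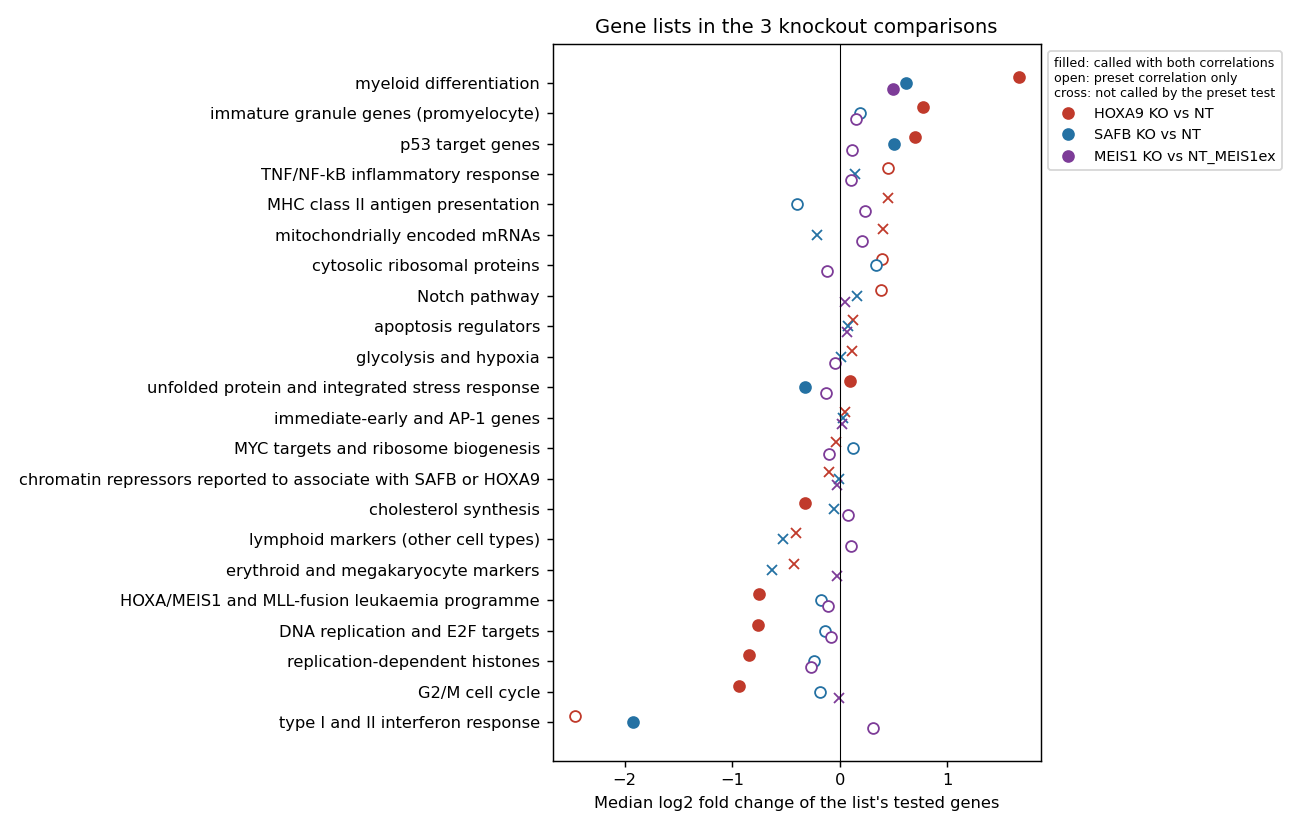
Median log2 fold change (x axis) of each gene list (y axis) in HOXA9_KO and SAFB_KO against NT and in MEIS1_KO against NT_MEIS1ex; filled points passed camera with both correlations, open points with the preset correlation alone and crosses did not pass. The myeloid list lies at 1.67, 0.62 and 0.50, and the interferon list at −2.46, −1.92 and 0.31; medians near 0 change sign with the scaling, such as the stress list in HOXA9_KO (0.10 to −0.16) and the MYC list in SAFB_KO (0.12 to −0.01).

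Genes that changed in both HOXA9_KO and SAFB_KO nearly all moved the same way. The largest shared rises included the IgA receptor gene FCAR and the calcium-binding protein genes S100A8 and S100A9, and the largest shared falls the interferon-response genes IFI44L and IFI27. The changes after HOXA9 knockout were mostly the larger ones. MGAM2 rose by 4.31 and 3.13 in HOXA9_KO and SAFB_KO, FCAR by 4.45 and 2.75, S100A9 by 4.10 and 2.34 and S100A8 by 3.79 and 2.08. HGFAC, IL22RA2, ADGRE3, CLEC1A, SLC26A11 and GPR82 completed the 10 largest shared rises. IFITM1 changed by −5.51 and −3.62, IFI44L by −4.70 and −3.53, SLC6A9 by −3.59 and −3.38, IFI27 by −4.18 and −3.12, ADM2 by −3.35 and −3.02 and STC2 by −2.93 and −3.15. IFIT1, INHBE, CHAC1 and USP18 completed the 10 largest shared falls.

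Of 5685 genes called in both knockouts, 5511 moved the same way (96.9%), 3183 higher and 2328 lower, where independent calls would share 1052 and 862. Higher calls depended on level in both. In HOXA9_KO and SAFB_KO 3175 and 2778 of 6559 genes were higher at 20 CPM or more, and 356 and 82 of 5693 under 1 CPM. The 1052 can therefore be too low. The median ratio of the SAFB_KO change to the HOXA9_KO change was 0.590. Across the 18876 genes, which are not independent replicates, the fold changes had Pearson's r 0.707 and Spearman's rho 0.722. Both comparisons use the same 3 NT libraries, and simulated data with no effect and shared controls gave a mean r of 0.448. They gave at most 1 shared call. Without any changed gene there are few calls to share, so that count does not measure what shared controls add. The 3 NT libraries do not divide into separate control sets of 2, so how much of the excess the common controls add was not measured.

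**Figure D3:**
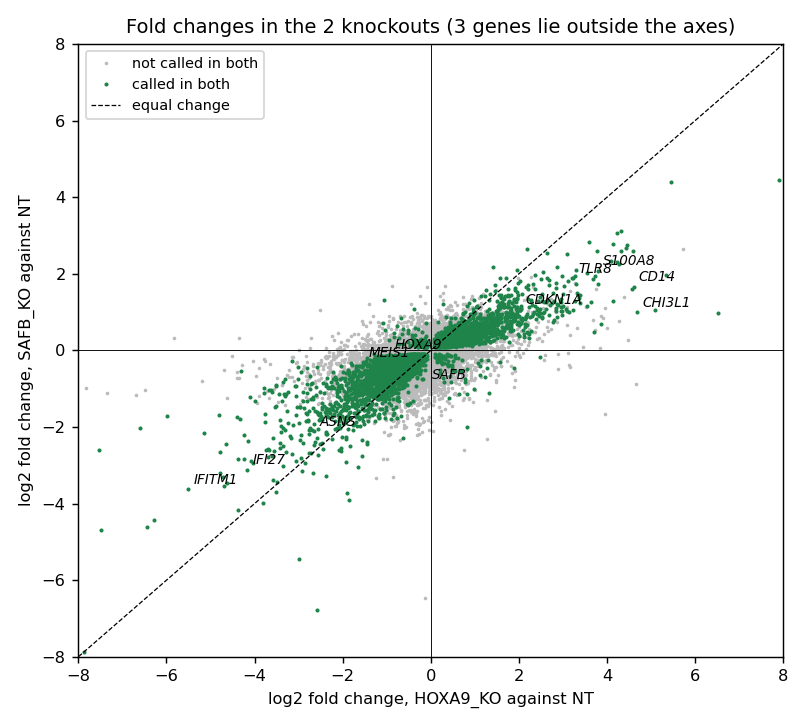
Log2 fold changes of each gene in HOXA9_KO (x axis) and SAFB_KO (y axis) against NT; green points are genes called in both, the dashed line marks equal change and 3 genes lie outside the axes. Of the genes called in both, 96.9% changed in the same direction, with a median ratio of 0.590.

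Setting HOXA9_KO directly against SAFB_KO takes the NT libraries out of the contrast, though they stayed in the filter, scaling and spread of the fit. A fit of only the compared groups called 3997 higher and 3692 lower genes. Myeloid genes were higher after HOXA9 knockout, and HOXA/MEIS1 programme, cell cycle, histone and cholesterol synthesis genes were lower. Of 40 myeloid genes 36 were higher (median 0.84, adjusted p 1.9e-54; adjusted p = 8.3e-04 with an estimated correlation), and of 34 programme genes 27 were lower and 3 higher (28 and 4 adjusted over the list alone; median −0.54, adjusted p 1.6e-16; adjusted p = 8.3e-04 with an estimated correlation). G2/M genes were lower in 34 of 35 cases (35 adjusted over the list alone; median −0.68, adjusted p 6.9e-39; adjusted p = 0.00371 with an estimated correlation). Histone genes were lower in 30 of 35 (31 adjusted over the list alone; median −0.55, adjusted p 5.8e-26; adjusted p = 0.00727 with an estimated correlation). A list without a second count in brackets had the same count adjusted over the list alone. MHC class II genes were higher in 10 of 16 cases and lower in 2 (median 0.65, adjusted p 8.2e-08; adjusted p = 0.0460 with an estimated correlation). Cholesterol synthesis genes were lower in 17 of 23 cases (median −0.29, adjusted p 2.1e-08; adjusted p = 0.0195 with an estimated correlation), and p53 targets higher in 20 of 31 and lower in 1 (median 0.27, adjusted p 2.1e-06; adjusted p = 0.0327 with an estimated correlation). Of 49 interferon genes 28 were lower and 3 higher (29 and 3 adjusted over the list alone; median −0.51, adjusted p 6.4e-05; adjusted p = 0.420 with an estimated correlation). The 4 recalled genes were all higher after HOXA9 knockout, by a median of 1.01. RNU6-1 (5.54), APOE (5.54), SNORA53 (4.21), CYP27A1 (4.05 ± 0.18, from 0.637 to 10.4 CPM) and SNORA74A (3.78) were highest relative to SAFB_KO, and TRDC (−3.02), TRD-AS1 (−2.87), ENPP2 (−2.81 ± 0.16), PDGFA (−2.60 ± 0.20) and TRAC (−2.59 ± 0.15) lowest. In all, 3791 genes were higher and 3877 lower, 539 and 569 of them at least 2-fold, with groups separated in 48.3% of genes against 10% by chance. Scaling to nuclear protein-coding counts shifted the median by −0.11 and gave 2449 higher and 5845 lower, or 29.5% higher against 49.4%.

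MEIS1 knockout, studied in an experiment of its own, raised myeloid genes with changes smaller than those of HOXA9 knockout. Histone genes and stress response genes were lower at the preset correlation alone (adjusted p = 0.131 and 0.142 with an estimated correlation). HOXA9, SAFB and PBX3 did not pass. The comparison asks which genes depend on MEIS1, a partner of HOXA9.

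Of 39 monocyte and granulocyte genes 29 rose and 1 fell (34 and 1 adjusted over the list alone), with a median of 0.50 (adjusted p 2.2e-39; adjusted p = 0.00872 with an estimated correlation). As before, a list without a further count in brackets had the same count adjusted over the list alone. The receptor gene CSF1R rose by 0.68 ± 0.05 from 52.5 to 84.3 CPM (adjusted p 5.3e-07), CYBB by 0.74 ± 0.06 from 69.2 to 116 CPM and CD86 by 0.66 ± 0.08. It was the only list of the 22 tested that also passed with an estimated correlation; all further lists of this comparison that passed did so with the preset correlation alone. Immature granule genes rose in 8 of 18 cases and fell in 2 (9 and 2 adjusted over the list alone; adjusted p 0.00669; adjusted p = 0.214 with an estimated correlation), MS4A3 rising by 0.90 ± 0.11 and CTSG falling by 0.40 ± 0.06. In the HOXA/MEIS1 list 5 of 33 genes fell and 2 rose (7 and 3 adjusted over the list alone, adjusted p 1.4e-04, and adjusted p = 0.0697 with an estimated correlation). MEIS1, the targeted gene, is a member and among the falls, and it adds to this result by design. BCL2 fell by 0.32 ± 0.05. HOXA9 changed by −0.11 ± 0.13 (adjusted p 0.686), HOXA7 by −0.13 (adjusted p 0.562), HOXA10 by −0.27 ± 0.09 (adjusted p 0.0747; 0.00754 with no filter, 0.0199 with all 17 libraries in the fit and 0.00955 without MEIS1_KO replicate 4, in a range of 0.00754 to 0.218) and PBX3 by −0.09 ± 0.05 (adjusted p 0.266). SAFB (−0.07, adjusted p 0.599), SAFB2 (0.01, adjusted p 0.966) and SLTM (0.09, adjusted p 0.535) did not pass either.

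Of the recalled genes 2 of 4 rose, again as no independent evidence: CDKN1A by 0.32 ± 0.04 (adjusted p 1.0e-04) and S100A8 by 1.19 ± 0.17 (adjusted p 6.3e-04). NOTCH1 changed by 0.07 (adjusted p 0.458) and CEBPD by −0.07 ± 0.27 (adjusted p 0.919). Notch pathway genes held 1 higher and 5 lower of 25 (3 and 6 adjusted over the list alone; median 0.05, mean −0.04 and test pointing down, adjusted p 0.900), HES1 falling by 1.25 ± 0.26. NOTCH2 rose by 0.23 ± 0.06 (adjusted p 0.0149), a call lost without MEIS1_KO replicate 1 (adjusted p 0.0585) and without NT_MEIS1ex replicate 3 (0.0637), in a range of 9.9e-04 to 0.0637. Of 31 p53 target genes 5 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.11, adjusted p 0.00112; adjusted p = 0.131 with an estimated correlation), BTG2 rising by 0.35 ± 0.05. Apoptosis regulators, 3 higher and 1 lower of 34, did not pass (adjusted p 0.258).

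Histone genes fell in 28 of 34 cases (32 adjusted over the list alone; median −0.26, adjusted p 4.1e-26; adjusted p = 0.131 with an estimated correlation), H2AC8 by 0.45 ± 0.05. Stress response genes fell in 12 of 30 cases and 1 rose (14 and 1 adjusted over the list alone; median −0.13, adjusted p 2.2e-09; adjusted p = 0.142 with an estimated correlation), TRIB3 by 0.75 ± 0.07 from 167 to 99.1 CPM and XBP1 by 0.53 ± 0.05. Interferon genes rose in 10 of 47 cases (17 adjusted over the list alone; median 0.31, adjusted p 3.8e-11; adjusted p = 0.307 with an estimated correlation), OAS3 by 0.91 ± 0.15. TNF and NF-kB genes rose in 7 of 32 cases and fell in 3 (10 and 3 adjusted over the list alone; median 0.10, adjusted p 0.00314; adjusted p = 0.273 with an estimated correlation; 0.380 at a mean of at least 20 CPM, range 3.7e-04 to 0.380), IL1B by 0.96 ± 0.13 and CCL3 by 1.01 ± 0.18. Mitochondrially encoded mRNAs rose in 7 of 13 cases (10 adjusted over the list alone; median 0.21, adjusted p 1.9e-07; adjusted p = 0.214 with an estimated correlation), MT-CYB by 0.25 ± 0.05.

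Small shifts made up the rest. Of 40 E2F genes 4 fell (5 adjusted over the list alone; median −0.08, adjusted p 6.7e-06; adjusted p = 0.274 with an estimated correlation), CDT1 by 0.38 ± 0.05. Of 40 MYC targets and ribosome biogenesis genes 8 fell (12 adjusted over the list alone; median −0.10, adjusted p 1.9e-06; adjusted p = 0.131 with an estimated correlation). Ribosomal protein genes fell in 3 of 50 cases (0 adjusted over the list alone in edgeR, median −0.12, adjusted p 5.9e-08, and adjusted p = 0.459 with an estimated correlation). At an unadjusted p under 0.05 in edgeR, 1 of them was higher and 29 lower, and DESeq2 called 5 and limma-voom 2 lower. MHC class II genes held 4 higher and 1 lower of 16 (5 and 1 adjusted over the list alone; median 0.24, adjusted p 0.0302; adjusted p = 0.459 with an estimated correlation; 0.198 at a mean of at least 20 CPM, range 9.7e-05 to 0.459). The call was also lost without MEIS1_KO replicate 3 (0.0539) or 4 (0.0903) or NT_MEIS1ex replicate 1 (0.0816) or 2 (0.228). Glycolysis and hypoxia genes held 1 higher and 2 lower of 31 (1 and 4 adjusted over the list alone; median −0.04, adjusted p 0.0320; adjusted p = 0.578 with an estimated correlation), a call also lost at a mean of at least 2 CPM (0.0641), at a mean of at least 20 CPM (0.0764) and scaled to nuclear protein-coding counts (0.0544), and without MEIS1_KO replicate 1 (0.149) or 2 (0.130) or NT_MEIS1ex replicate 3 (0.104) or 4 (0.102), in a range of 0.00294 to 0.578. DDIT4 fell by 0.58 ± 0.08. No cholesterol synthesis gene of 23 was called by edgeR over all genes, where 7 were higher at an unadjusted p under 0.05, 5 rose when adjusted over the list alone, and DESeq2 called 3 and limma-voom 0 higher (median 0.08, adjusted p 0.0320; adjusted p = 0.481 with an estimated correlation). The call of this list was also lost without MEIS1_KO replicate 3 (0.0546) or 4 (0.157) or NT_MEIS1ex replicate 1 (0.0816) or 2 (0.0577), in a range of 0.00764 to 0.481. Lymphoid genes held 2 higher and 1 lower of 10 (3 and 1 adjusted over the list alone; median 0.10, adjusted p 0.0159; adjusted p = 0.131 with an estimated correlation), IL7R rising by 0.89 ± 0.07 from 24.1 to 44.7 CPM. G2/M genes held 2 lower of 35 (0 adjusted over the list alone in edgeR), and their list did not pass (adjusted p 0.233). At an unadjusted p under 0.05 in edgeR, 2 of them were higher and 8 lower, and DESeq2 called 2 and limma-voom 1 lower. Not passing either were immediate-early genes with 1 higher and 2 lower of 28 (median 0.02, mean 0.04 and test pointing down, adjusted p 0.900), chromatin repressor genes with 1 higher and 3 lower of 28 (1 and 4 adjusted over the list alone; adjusted p 0.121) and erythroid and megakaryocyte genes with 1 higher of 5 (median −0.02, mean 0.12 and test pointing up, adjusted p 0.562).

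The largest rises in MEIS1_KO were those of the receptor gene TNFRSF14 (1.68 ± 0.14, from 1.75 to 5.62 CPM), MGAM2 (1.57 ± 0.26), HP (1.33 ± 0.17), the chemokine gene CXCL8 (1.31 ± 0.19, from 8.40 to 20.9 CPM), CLEC10A (1.24), S100A8 (1.19), PRLR (1.18), OLFML3 (1.17), SIGLEC1 (1.12 ± 0.10, from 48.6 to 106 CPM) and NAV3 (1.08). The largest falls were those of KLHDC7B (−2.18 ± 0.29), MEIS1 (−1.54), PLXNC1 (−1.30 ± 0.09, from 37.3 to 15.2 CPM), ADGRG3 (−1.28), OCSTAMP (−1.02), RGS16 (−0.99), IRGM (−0.99), MFAP4 (−0.96), CST7 (−0.93) and S100P (−0.93). In edgeR's test of 15744 genes 783 were higher and 604 lower, 37 and 18 of them at least 2-fold. Groups were separated in 15.7% of the genes, which chance gives in 2.86% for 4 against 4. Leaving out single libraries gave 487 to 944 higher and 264 to 828 lower genes, with 362, 327 and 264 lower without MEIS1_KO replicates 1, 2 and 3 and 388 and 324 lower without NT_MEIS1ex replicates 3 and 4. The higher count was 487 without MEIS1_KO replicate 3. Scaling to nuclear protein-coding counts gave 979 higher and 450 lower genes, or 68.5% higher against 56.5%.

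Genes called in both HOXA9_KO and MEIS1_KO moved the same way in 982 of 1157 cases, 607 higher and 375 lower, where independent calls would share 252 and 184. The shared rises included TNFRSF14 (1.83 and 1.68), HP (3.13 and 1.33), CXCL8 (3.55 and 1.31) and the hexokinase gene HK3 (1.94 and 1.04), and the shared falls PLXNC1 (−1.63 and −1.30), OCSTAMP (−2.98 and −1.02), TRIB3 (−1.01 and −0.75) and GATA2 (−1.26 and −0.71). The fold changes had r 0.238 and rho 0.167 across 15504 genes. SAFB_KO and MEIS1_KO shared 773 of 921 genes called in both, 512 higher and 261 lower, where 189 and 95.5 would be shared by independent calls. Among them VCAN rose by 1.52 and 1.02, NAV3 by 1.46 and 1.08 and S100A9 by 2.34 and 1.001, while RGS16 changed by −1.03 and −0.99. These fold changes had r 0.160 and rho 0.104. Calls in MEIS1_KO depended on level too. At 20 CPM or more 461 were higher and 458 lower of 7503 genes, and under 1 CPM 34 and 13 of 2643. The numbers for independent calls can therefore be too low. The count shared by HOXA9_KO and MEIS1_KO was 598 without MEIS1_KO replicate 3.

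The change after HOXA9 knockout differed from that after MEIS1 knockout in 8321 of 18836 genes in a test of the difference, 4618 towards higher and 3703 towards lower. Myeloid genes rose more after HOXA9 knockout (35 of 41, median difference 1.12; adjusted p = 2.6e-04 with an estimated correlation), and p53 targets did so too (26 of 31, 1 the other way, median 0.74). G2/M genes (34 of 35, median −0.90) and interferon genes (45 of 49, 1 the other way, 46 and 1 adjusted over the list alone, median −2.73) differed towards lower. RNU6-1 (8.35), CYP27A1 (4.65), APOE (4.57), SNORA53 (4.33) and SLC26A11 (4.27) had the largest positive differences, and IFITM1 (−5.82), OTOF (−5.41), IFI44L (−5.27) and IFI27 (−4.83) large negative ones. NR2F1, also among the 5 largest, is near the floor and has no fold here. The SAFB knockout effect differed from the MEIS1 effect in 3930 genes, 2330 towards higher and 1600 towards lower. p53 targets (24 of 31, 2 the other way, median 0.45; adjusted p = 0.00127 with an estimated correlation) and interferon genes (47 of 49, median −2.28; adjusted p = 0.00127 with an estimated correlation) differed, and among single genes FCAR (2.10 ± 0.23), GDF15 (1.86), GPR82 (1.69), MGAM2 (1.56) and CKAP4 (1.56) upwards and IFI44L (−4.14), IFITM1 (−3.97), IFI27 (−3.81) and IFIT1 (−3.71) downwards; ST6GALNAC3 is near the floor and has no fold here. Scaling to nuclear protein-coding counts shifted the medians of these differences by −0.32 and −0.17 and left 19.4% and 14.9% of the calls higher, against 55.5% and 59.3%. The experiments differ in rRNA share (25.1% in NT, at most 0.0101% in the MEIS1 experiment) and in interferon level, so these differences hold the knockout and the experiment together.

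**Figure D4:**
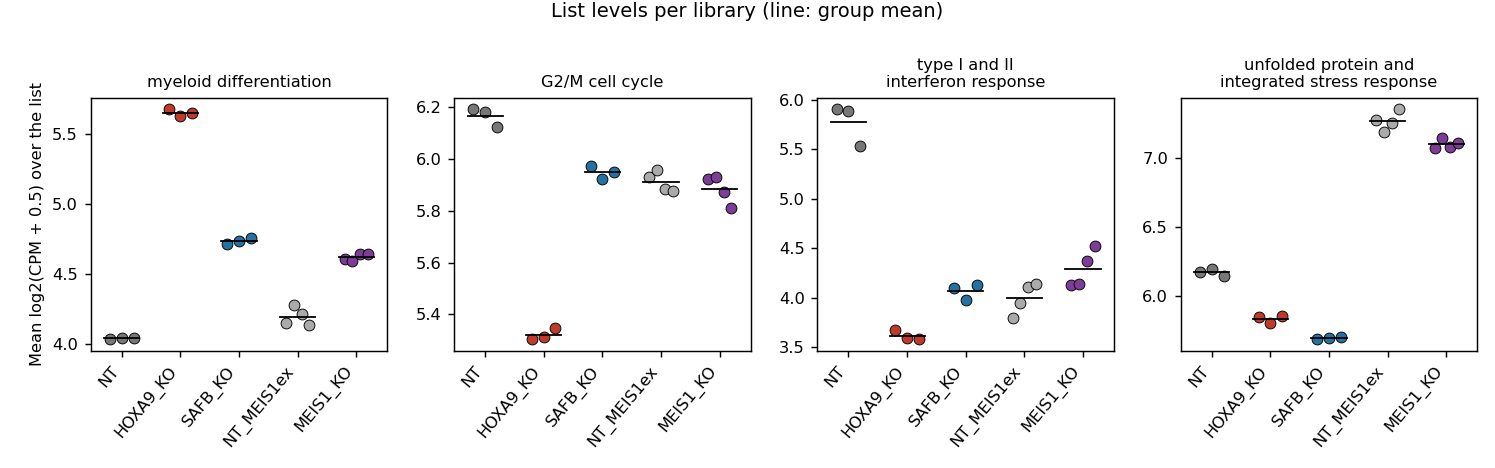
Mean log2(CPM + 0.5) over 4 gene lists (y axes) in each library of the 5 groups (x axes); points are libraries and lines are group means. The interferon list averages 5.77 in NT against 3.61 to 4.29 in the other 4 groups.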

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

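The tests of the patterns weighed here were chosen after the results were seen; the tests for stray libraries, the differences between effects and the splits of the libraries were planned.

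In a check for a library far from the rest of its group, 7 of 132 sets of 4 libraries stood out, where chance gives about 1 in 20, or 6.6. HOXA9 lay at 38.7 CPM in NT_MEIS1ex replicate 4 against 47.9 to 48.9 in the other 3 libraries. CST7 in the same library lay at 21.9 CPM against 16.4 to 17.2. In MEIS1_KO replicate 4, ADGRG3 lay at 1.21 CPM against 0.952 to 0.967, BTG2 at 91.6 CPM against 82.1 to 83.4 and CTSG at 85.6 CPM against 93.9 to 95.1. In MEIS1_KO replicate 2, HES1 lay at 1.25 CPM against 0.788 to 0.856 and TRIM22 at 149.6 CPM against 155.4 to 156.4.

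The effects of 2 knockouts differed in 8321 genes between HOXA9 and MEIS1 and in 3930 genes between SAFB and MEIS1, by a test of the difference itself. Genes called in opposite directions numbered 175 between HOXA9_KO and MEIS1_KO and 148 between SAFB_KO and MEIS1_KO. Both knockouts of the first experiment stand against NT and MEIS1_KO stands against NT_MEIS1ex, so each difference is also one between experiments. Reads that fell in more than 1 gene, which no comparison uses, made up 7.64% of the reads in HOXA9_KO and 6.91% in SAFB_KO against 6.31% in NT.

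Other splits of the libraries were fitted for each comparison. For HOXA9_KO, SAFB_KO and HOXA9_KO against SAFB_KO, 10 splits are too few for a share under 0.05; the real splits gave 10847, 6698 and 7668 genes, as the only 1 of 10 to reach that number in each, and the highest other split gave 0. For the lists of HOXA9_KO and SAFB_KO the 10 splits are again too few: the real values were 13 and 12 lists and the highest of the others 13 and 11, with 2 and 1 of 10 splits as large. The lists of HOXA9_KO are thus matched by another split at the preset correlation. For the genes of MEIS1_KO only the real split, 1 of 35, reached 1387 (highest other 0), the smallest share that 35 splits can give. This argues against a chance sorting of these libraries. A difference between the groups other than the knockout would give the same result. For lists 1 of 35 splits reached 16, but the highest other gave 15 and leaving out single libraries gave 14 to 15, so the lead of the real split is no larger than its spread and chance is not excluded for their number. For shared genes of HOXA9_KO and SAFB_KO, 1 of 60 splits reached 5511 (highest other 4758), and for the differences from the MEIS1 effect 1 of 40 splits each reached 8321 genes (highest other 7628) and 3930 genes (highest other 3850). These shares lie under 0.05, but drawn splits of these kinds can hold whole real groups under other names. For genes shared with MEIS1_KO, 982 with HOXA9_KO and 773 with SAFB_KO, the highest other of 100 splits gave 0. Because the other splits of a single comparison call 0 genes, they can share none, so these splits do not test whether the overlap exceeds chance.

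Interferon-response genes were lower in both HOXA9_KO and SAFB_KO than in NT, where the list of HOXA9_KO passed at the preset correlation alone (adjusted p = 0.0684 with an estimated correlation). Across experiments, the list's members stood 1.96 (median, log2) higher in NT than in NT_MEIS1ex, 44 of 49 above, while HOXA9_KO and SAFB_KO stood at −0.42 and 0.18 relative to NT_MEIS1ex. An interferon state of the NT libraries may therefore account for much of the fall, but NT is confounded with its experiment, and a fall caused by each knockout from a level common to that experiment stays open. Between HOXA9_KO and SAFB_KO, a contrast that NT does not enter, 31 of 49 members were called. In HOXA9_KO 28 were lower and 3 higher (camera adjusted p = 0.420 with an estimated correlation for the list). SAFB_KO can carry part of such a state, so this does not show that HOXA9_KO fell for another reason, and the state as the whole account stays open.

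Changes in SAFB_KO followed those in HOXA9_KO. Chance values of the shared NT libraries are argued against by the covariance of the fold changes, 0.318, where simulated data with shared controls and no effect reached at most 0.0258. Of the shared genes 58.1% were called between the knockouts (3201 of 5511), and 3102 of these had the larger change in HOXA9_KO. A state of the NT libraries, in part or as the whole account, stays open all the same, because SAFB_KO can carry part of it and the experiment has no other controls. For the myeloid list, which rose in both, the values went against it: its members stood 0.17 (median, log2) higher in NT than in NT_MEIS1ex, 23 of 41 above, and HOXA9_KO and SAFB_KO stood at 1.41 and 0.66. These values do not exclude it, because other lists differed between the 2 control groups by −1.28 to 1.96, so an experiment could shift a list by as much. A shared effect of losing either protein on the leukaemia programme may be a further account: 59.2% of 5203 shared genes moved the same way in MEIS1_KO, but other splits of those libraries gave up to 71.1%, so this test leaves it open.

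Genes of low level had lower median changes than abundant genes in HOXA9_KO and SAFB_KO, and more of their falls were at least 2-fold. Genes under 1 CPM had a median change of −0.46 in HOXA9_KO and −0.35 in SAFB_KO, against 0.10 and 0.09 at 20 CPM or more, and 1186 of 5693 fell at least 2-fold in HOXA9_KO against 175 of 6559. Calls of any size in HOXA9_KO numbered 356 higher and 1425 lower under 1 CPM and 3175 higher and 1854 lower at 20 CPM or more, and in SAFB_KO 82 and 639 against 2778 and 932. Reads outside annotated genes made up 17.04% in NT against 9.02% in HOXA9_KO. More background reads in the NT libraries may account for falls at low levels, but the median of −0.46 is the pattern itself and no test here could decide it; a biological account was not tested. For the 175 abundant genes, whose median loss was 41.3 CPM, background was not decided either, because choosing abundant genes with a 2-fold fall fixes a large loss.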

How the results depend on the processing

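The scaling to nuclear protein-coding counts and the mean of at least 20 CPM were chosen after seeing the data. Of 308 alternative values of the 16 counts, 280 lay within 1.5 times the reported count and 28 did not. Of 4136 values for 231 results of named genes, in which a gene recurs across comparisons, 4097 kept their direction and side of the threshold, 22 passed it, 15 lost it and 2 reversed, in 11 of the results. Of 956 values for 66 list results, 887 kept both, 20 passed and 49 no longer passed, 27 of these with an estimated correlation.

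Scaled to nuclear protein-coding counts, HOXA9_KO had 2861 higher and 9293 lower genes, SAFB_KO 1712 and 5535, and HOXA9_KO against SAFB_KO 2449 and 5845, with median shifts of −0.25, −0.14 and −0.11. SAFB2 and SLTM in HOXA9_KO reversed to −0.14 and −0.17 (adjusted p 0.0233 and 7.7e-05; ranges over the alternatives 0.0233 to 0.971 and 7.7e-05 to 0.550), a move that this shift of all genes makes. Both were called higher with RLE factors (adjusted p 0.0293 and 0.00725), DESeq2 (0.0446 and 0.0101) and a fit of only the compared groups (0.0299 and 0.0109). HOXA9 in SAFB_KO passed at −0.25 (adjusted p 7.0e-05, range 7.0e-05 to 0.244) and SAFB in HOXA9_KO at −0.36 (1.5e-05, range 1.5e-05 to 0.493). Other settings called them too: HOXA9 at a mean of at least 2 CPM (−0.17, 0.00541) and with limma-voom (0.0458), SAFB at a mean of at least 2 CPM (−0.16, 0.0286) and without NT replicate 2 (−0.19, 0.00951). A filter on mean CPM also rescales the libraries. Genes of at least 20 CPM had main medians of 0.10 in HOXA9_KO and 0.09 in SAFB_KO. Filtered at 20 CPM, the medians were −0.01 and −6.2e-04. Calls with that filter thus hold a shift of abundant genes towards lower, and the shift at 2 CPM was not measured.

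At a mean of at least 20 CPM fewer genes were tested, 6569 in the first experiment and 7197 over both. HOXA9_KO then had 2501 higher and 2584 lower genes, SAFB_KO 1721 and 1725, and HOXA9_KO against SAFB_KO 2140 and 2179. The differences from the MEIS1 effect fell to 4361 and 1986 genes, and the shared genes to 2997 for HOXA9_KO and SAFB_KO and 652 for HOXA9_KO and MEIS1_KO. At an adjusted p under 0.01, HOXA9_KO and MEIS1_KO shared 516 genes and SAFB_KO and MEIS1_KO 423, as a stricter threshold must lower them. With all 17 libraries in the fit, MEIS1_KO had 1165 lower genes; the cause was not tested. With an estimated correlation 4 lists passed in SAFB_KO and 1 in MEIS1_KO, against 12 and 16. Camera's p-values rise with this correlation. Against the preset 0.01, estimates were 0.735 for ribosomal protein and 0.609 for histone genes in MEIS1_KO, and 0.426 for ribosomal protein genes in SAFB_KO. In MEIS1_KO the HOXA/MEIS1 and lymphoid lists were lost at estimates of 0.00833 and 0.00141, so a higher correlation is not the whole account.

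Leaving out single libraries gave 487 to 944 higher and 264 to 828 lower genes in MEIS1_KO, 598 to 1201 shared with HOXA9_KO and 516 to 878 shared with SAFB_KO. The lowest 3 counts of lower genes came without MEIS1_KO replicate 3 (264), NT_MEIS1ex replicate 4 (324) and MEIS1_KO replicate 2 (327), followed by MEIS1_KO replicate 1 (362) and NT_MEIS1ex replicate 3 (388). HOXA9_KO ranged over 4938 to 5382 higher and 5057 to 5682 lower genes, SAFB_KO over 3290 to 3886 and 2256 to 2939, and their shared genes over 4683 to 5405. MHC class II genes in MEIS1_KO no longer passed without MEIS1_KO replicate 3 or 4 or NT_MEIS1ex replicate 1 or 2 (adjusted p 0.0539, 0.0903, 0.0816 and 0.228), nor cholesterol synthesis genes without the same libraries (0.0546, 0.157, 0.0816 and 0.0577). Glycolysis genes no longer passed without MEIS1_KO replicate 1 or 2 or NT_MEIS1ex replicate 3 or 4 (0.149, 0.130, 0.104 and 0.102).

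DESeq2 called 5449 higher and 4850 lower genes in HOXA9_KO, 3867 and 2318 in SAFB_KO and 836 and 775 in MEIS1_KO. Libraries were not treated as pairs: residual correlations of libraries with the same number were −0.037 to 0.019 for NT and HOXA9_KO, −0.032 to 0.086 for HOXA9_KO and SAFB_KO and −0.276 to 0.0918 in the MEIS1 experiment. For NT and SAFB_KO they were 0.0211 to 0.0484, above those of all other pairs (−0.047 to 0.00738), but small. A replicate block gave 5188 higher and 5599 lower genes in HOXA9_KO, 3843 and 2875 in SAFB_KO, 729 and 466 in MEIS1_KO and 3786 and 3856 between HOXA9_KO and SAFB_KO. The block gave 8090 and 3703 genes for the 2 differences, 5539, 868 and 715 shared genes and 13, 12 and 16 lists, and changed no call of a named gene or list. In simulated data 63.5%, 68.8% and 72.0% of genes changed by 0.5 on the log2 scale were recovered for HOXA9_KO, SAFB_KO and MEIS1_KO. Genes of such a change can therefore go uncalled, and depth itself was not varied. The simulation changed 200 genes and 1 list, while 10847 genes were called in HOXA9_KO and 6698 in SAFB_KO. With few changed genes the adjusted threshold is stricter, so these shares can understate the recovery in the data.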

Other observations

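The lists in this part were chosen after seeing the data, from genes that stood out, and are descriptive.

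Lysosomal genes rose in 40 of 43 cases and 1 fell in HOXA9_KO (median 1.14; camera adjusted p = 0.00372 with an estimated correlation). In SAFB_KO 34 rose and 1 fell (median 0.46; adjusted p = 0.0150 with an estimated correlation), and in MEIS1_KO 21 rose (median 0.18; adjusted p = 0.0212 with an estimated correlation). Set against SAFB_KO, 40 of the 43 genes were higher and 1 lower in HOXA9_KO (median 0.69; adjusted p = 0.00312 with an estimated correlation). Nuclear genes of the respiratory chain rose in 37 of 42 cases in HOXA9_KO (median 0.36; adjusted p = 0.167 with an estimated correlation) and in 31 in SAFB_KO (median 0.15; adjusted p = 0.127 with an estimated correlation), and 1 rose and 1 fell in MEIS1_KO (median −0.03; adjusted p = 0.748 with an estimated correlation).

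Several classes of non-coding genes held more lower than higher calls in the first experiment, where genes of low level in general had lower medians. Of 1684 tested antisense genes 123 were higher and 485 lower in HOXA9_KO (median −0.41, camera adjusted p 0.0511; adjusted p = 0.167 with an estimated correlation) and 45 and 268 in SAFB_KO (median −0.31, adjusted p 7.4e-04; adjusted p = 0.0381 with an estimated correlation). Because the strand setting of the counts is not given in the sources used here, reads of the sense genes cannot be set apart from them. Of 1008 long intergenic RNA genes 146 were higher and 269 lower in HOXA9_KO (adjusted p 0.260; adjusted p = 0.296 with an estimated correlation) and 57 and 149 in SAFB_KO (adjusted p 0.0196; adjusted p = 0.0547 with an estimated correlation). Of 113 small nucleolar RNA genes 12 were higher and 22 lower in HOXA9_KO, and of 95 small nuclear RNA genes 19 and 20 (adjusted p 0.832 for each; adjusted p = 0.817 with an estimated correlation). Of 1140 processed pseudogenes 95 were higher and 294 lower in HOXA9_KO (median −0.46, adjusted p 0.131, and adjusted p = 0.167 with an estimated correlation). In SAFB_KO 55 were higher and 150 lower (median −0.32, adjusted p 0.0175, and adjusted p = 0.0454 with an estimated correlation). No class among these passed in HOXA9_KO. RNU6-1 went from 0.328 to 30.7 CPM.

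Levels of several lists differed between the control groups of the 2 experiments. Relative to NT_MEIS1ex, NT stood at a median of −1.07 for the stress response list, −0.99 for immediate-early genes, −1.16 for histone genes and −1.28 for mitochondrially encoded mRNAs.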
